A study of Mus musculus with 2 samples.

How the data were processed

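The series holds total RNA sequencing of heart tissue, made from 300 ng of RNA per library with a directional kit after reduction of ribosomal RNA and with ERCC spike-ins, per the labels. Reads were aligned to mm10 with the GENCODE M21 annotation, per the deposited readme. The aligner and the versions of the quantification tools are not given in the sources used here. Each library came with a gene table and a transcript table in the column layout of RSEM, called the first quantification, and a transcript table in the layout of kallisto, called the second quantification.

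Per the file headers, the gene and transcript tables give expected counts, in which reads shared by several entries are split by an estimator. The deposited TPM values are scaled by the authors to the same total over all entries, spike-ins included. The deposited FPKM values were used only as an alternative. The deposited transcript tables also hold the percent of a gene's abundance held by each transcript, and the shares given here were computed from transcript TPM in the same way for both quantifications. The second quantification gives estimated counts and TPM per transcript, per the file headers, and its values were summed per gene here. It covers 141767 of the 141862 annotated transcripts. In the first quantification, effective length was 100 bases below length for the spike-ins, so an entry of at most 100 bases gets no value. This holds for 2452 annotated genes, of which 0 had counts.

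Each gene table held 55536 annotated genes, 26248 numbered entries with a median length of 73 bases, 96 spike-ins and a phiX entry. Numbered entries and phiX were left out, the former with 3 and 2 expected counts in library 1 and library 2 and the latter with 187 and 216. Total expected counts were 39819960 and 37060119, and 42977135 and 38957328 in the second quantification. At this depth a count of 0 allows 3 counts, and intervals and floors cover counting error only. Names, gene types and coordinates came from the GENCODE M21 annotation. All listed symbols were found, 1 of them (Ctgf, now Ccn2) through the synonyms in the RefSeq table. Where a symbol had several entries, the one with the highest mean TPM was used.

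Groups were read from the labels, which give 1 group of 2 libraries. No test between groups was possible, and no p-value was computed. Choices of gene lists, measures, naming rule and most alternatives were fixed before the data were examined. A gene counted as detected at a TPM of at least 1 in both libraries. The log2 ratio was log2((TPM of library 2 + 1)/(TPM of library 1 + 1)), which understates the ratio of low genes. A 2-fold ratio was asked of genes with a rounded expected count of at least 10 in a library and a mean TPM of at least 1. Sampling noise was given by 100 Poisson draws. Expected counts were rounded for edgeR 4.0.16 (TMM factors, filterByExpr, 14851 genes kept), which estimated the common dispersion with an intercept-only design. Lists with at least 5 genes above a mean of 1 TPM were set against 10000 random lists of the same size matched on mean TPM in 20 bins, as the percentile of the median log2 ratio. Ratios of expected counts carry an exact (Clopper-Pearson) 95% interval from the conditional binomial. Copies of mitochondrial genes were aligned to them with Biopython 1.88. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and DESeq2 1.42.0, the last for size factors only.

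Named genes were the first members by mean TPM of the fixed lists under discussion (up to 4 with values), all sex-linked genes, App and Thy1, the 10 nuclear entries with the highest mean TPM, the 10 genes with the largest log2 ratio in each direction among those with a mean TPM of at least 5 and 100 counts in the higher library (12 on the library 2 side because 4 were tied), and the leading transcript of each isoform gene. Other named genes, among them Mb, Irx4, Ucp3, Per2, Nr1d1, Egr1, Jun, Tnni1 and the myosin transcripts, were chosen after their values were seen. Some genes that the rule takes are not reported here.

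The steps were tested on simulated libraries with the means and sizes of the real ones. With a coefficient of variation of 0.1 and no gene changed, edgeR estimated 0.100 over 14986 genes, and 0.140 over 14989 genes with 200 genes changed, so genes that truly differ raise the estimate. The 2-fold rule found 100% of 50 genes raised at a log2 fold of 2 and 95.9% of 49 lowered by as much. At a log2 fold of 1.3 it found 84% of 50 raised and 56% of 50 lowered, and it passed 0 of 12507 unchanged genes. The rule was applied there to simulated gene counts scaled by library total, not to TPM. Errors from splitting shared reads or from the lengths of assigned transcripts were not simulated. The values thus do not give the rate of false calls in the real libraries. A list of 10 genes raised 1.3-fold reached percentile 100, and 3.5% of 200 unchanged lists lay outside the range that holds 95% of random lists. Alternatives were other pseudocounts, filters, scalings and units, the second quantification, and each library alone.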

Results

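Total RNA was profiled from heart tissue of male mice aged 8 to 10 months from a cross of 5xFAD with CAST. 5xFAD is a transgenic mouse line made to model amyloid deposition in the brain, and CAST is a wild-derived inbred strain. The data comprise 1 group of 2 libraries, labelled biological replicates 1 and 2 and called library 1 and library 2 here. The labels give both libraries separate tissue samples but the same donor identifier, so the spread between them may be technical or biological and is stated only as a spread between these samples. With a single group there was no contrast between conditions. The questions the data can answer are which genes the heart expressed, at what level, and how closely the replicates matched. Library 1 held 39819960 expected counts and library 2 held 37060119. Values below are TPM, the abundance of transcripts scaled for length and library total, as mean ± SD over the libraries (n = 2), unless a library is named.

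Mitochondrial transcripts held the largest share of TPM in these libraries, from which ribosomal RNA had been reduced. The 13 mitochondrial mRNAs held 20.02% ± 0.330 of the TPM of annotated genes, and the 2 mitochondrial ribosomal RNAs held 23.1% ± 0.440. Among the mRNAs, the cytochrome oxidase subunits mt-Co1 and mt-Co3 stood at 39552 ± 811 and 35205 ± 857 TPM, the ATP synthase subunit mt-Atp6 at 23353 ± 1228 and cytochrome b, mt-Cytb, at 21698 ± 675. Nuclear protein-coding genes held 32.9% ± 0.00957. By expected counts, which are not divided by length, nuclear protein-coding genes led with 54.0% ± 0.280, against 14.8% ± 0.164 for the mitochondrial mRNAs and 23.3% ± 0.209 for the mitochondrial ribosomal RNAs. Short structural RNAs, annotated as miscellaneous RNA, held 13.7% ± 1.06 of the TPM but only 2.33% ± 0.194 of the expected counts. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA whose values were equal in every library, stood at 60398 ± 5653 TPM each, and Rn7sk, a regulator of transcription elongation, at 15328 ± 678.

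The 10 nuclear entries with the highest mean TPM were Rn7s1, Rn7s2, Gm28661, Gm10925, Rn7sk, Gm29216, Myl2, Mb, Myh6 and Gm26917. Gm26917, annotated as a long non-coding RNA on chromosome 17 (39843013 to 39846341, plus strand), stood at 4502 ± 178 TPM. Its gene type is that of the annotation, and the source of its reads was not tested. Of these entries, 3 are pseudogene copies of mitochondrial genes that lie side by side on the minus strand of chromosome 1 (mm10). Gm28661 (24614885 to 24615565) aligned to mt-Co2 over 681 bases with 0 mismatches, and Gm10925 (24613974 to 24614651) to mt-Atp6 over 678 bases with 0 mismatches. Gm29216 (24615706 to 24616197) aligned to mt-Co1 over 483 bases with 1 mismatch. Gm28661 was listed at 38510 ± 1057 TPM while mt-Co2 itself was listed at only 857 ± 88.3. The second deposited quantification gave Gm28661 30739 ± 1225 and mt-Co2 5832 ± 625 TPM. For Gm10925 the quantifications differed more, with 18398 ± 1973 TPM in the first and 0.610 ± 0.102 in the second. Reads that lie in a stretch without mismatches cannot be assigned by sequence, so the values of mt-Co2, mt-Atp6, mt-Co1, mt-Nd4l and their chromosome 1 copies are uncertain. So is that of mt-Co3. The second quantification listed mt-Co3 at 18898 ± 703 TPM and mt-Atp6 at 38183 ± 353, so their order was reversed. With these copies and Gm10222, a copy of mt-Nd4l, added, the mitochondrial mRNA share was 27.1%, a sum chosen after seeing the data. TPM is divided by length, and Gm29216 has 492 bases against 1545 for mt-Co1. The plain sum thus weighs a read on Gm29216 more than a read on mt-Co1. The overlapping mt-Atp8 was also uncertain, at 10720 ± 384 TPM in the first quantification and 106 ± 130 in the second.

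Contractile genes led the nuclear protein-coding transcripts. The sarcomere list held 7.48% ± 0.163 of the TPM outside the mitochondrial chromosome and 12.9% ± 0.103 of that of nuclear protein-coding genes. It held 12.8% of the expected counts outside that chromosome, which are not divided by length. Of its 22 members, 21 had a mean TPM of at least 1. The ventricular regulatory light chain Myl2 stood at 7558 ± 281 TPM (13390 in the second quantification), the adult myosin heavy chain Myh6 at 6765 ± 206, cardiac actin Actc1 at 4394 ± 93.7 and tropomyosin Tpm1 at 3799 ± 59.7. The exception was the slow skeletal troponin Tnni1, at 0.215 ± 0.106. Myoglobin, Mb, stood at 6871 ± 93.2. In the calcium handling list, the sarcoplasmic reticulum pump Atp2a2 stood at 3812 ± 19.8 TPM, its inhibitor phospholamban, Pln, at 2301 ± 19.1, the calcium-binding proteins Hrc and S100a1 at 378 ± 12.7 and 376 ± 0.474, and all 12 members were above 1. Among conduction and channel genes the gap junction protein Gja1 was at 112 ± 2.09. Cardiac transcription factors were lower, with Mef2a at 44.2 ± 0.226, Mef2d at 44.0 ± 0.474, Gata4 at 38.7 ± 2.52 and Mef2c at 29.1 ± 2.04.

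Myh6 (chromosome 14, 54941921 to 54966927, minus strand) held 90.0% ± 0.502 of the summed TPM of Myh6 and its neighbour Myh7 (54970684 to 54994626, minus strand), the heavy chain of the fetal ventricle and of slow muscle. Most of the Myh7 value came from a single short entry. Myh7-206, a retained-intron transcript of 595 bases, held 77.1% ± 3.36 of the Myh7 TPM at 582 ± 10.8, and the full-length Myh7-201 stood at 172 ± 29.0. Short entries also held part of the Myh6 TPM, with Myh6-207 (542 bases) at 33.8% ± 0.811 and Myh6-202 (376 bases) at 6.86% ± 1.14. Over coding transcripts above 5000 bases, the Myh6 share was 95.8% ± 0.774. This restriction was chosen after seeing the data. These heavy chains are close paralogs, so reads shared between them make both values uncertain. The ratio of the atrial light chain Myl7 to the ventricular Myl2 was 0.0374 ± 0.00726, with 0.0323 in library 1 and 0.0426 in library 2, and 0.0208 on average in the second quantification. Myl2-210, a processed transcript of 467 bases not annotated as protein coding, held 33.0% ± 1.77 of the Myl2 TPM. In the second quantification it stood at 7594 ± 226 TPM and the protein-coding Myl2-201 at 0. The Myl2 level and this ratio thus depend on the value given to a short entry. The stress-associated natriuretic peptide Nppb stood at 42.3 ± 1.82 TPM, the stress-induced Ankrd1 at 405 ± 22.7 and skeletal actin Acta1 at 195 ± 16, against 730 ± 159 for Nppa, which is also an atrial hormone.

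Genes of fatty acid use were abundant. All 19 members of the fatty acid oxidation list were above 1 TPM, led by the fatty acid carrier Fabp3 at 2296 ± 147, lipoprotein lipase, Lpl, at 1131 ± 6.39, the trifunctional protein subunit Hadhb at 777 ± 51.5 and the fatty acid transporter Cd36 at 631 ± 0.608. The list held 2.79% ± 0.119 of the TPM of nuclear protein-coding genes and the glycolysis list 2.05% ± 0.0175. The citric acid cycle list held 1.68% ± 0.0235 and the nuclear respiratory chain list 3.93% ± 0.0342. The fatty acid oxidation list includes Fabp3, Lpl and Cd36, which are not oxidation enzymes. These shares thus depend on list membership and do not rank the pathways. Atp5b, a subunit of ATP synthase, led the respiratory chain list at 2550 ± 57.3 TPM, Idh2 the citric acid cycle list at 801 ± 22.1 and Gapdh the glycolysis list at 1562 ± 67.8. The heart form of lactate dehydrogenase, Ldhb, exceeded Ldha 4.29-fold ± 0.0815, and the muscle form of carnitine palmitoyltransferase, Cpt1b, exceeded Cpt1a 9.95-fold ± 0.786.

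Markers of the other cell types of the heart were present at lower levels. All 14 endothelial markers were above 1 TPM, with a median of 28.0 ± 0.880, led by Fabp4 at 262 ± 13.8, Aqp1 at 125 ± 5.20, Ly6c1 at 64.0 ± 1.73 and Egfl7 at 53.1 ± 2.55. All 11 fibroblast markers passed the same level, with Gsn at 222 ± 10.97, Dcn at 115 ± 6.31, Dpt at 27.9 ± 0.757 and Col3a1 at 24.0 ± 0.0919 (36.5 in the second quantification). Pericyte and smooth muscle lists were led by Rgs5 at 86.6 ± 5.93 and Smtn at 58.7 ± 0.0990. Macrophage genes were lower, with C1qb at 11.9 ± 0.467 TPM, C1qa at 11.6 ± 0.226 and 10 of 12 members above 1. The mesothelial markers Upk3b and Msln stood at 5.38 ± 0.884 and 4.64 ± 0.764. Blood was represented by the globins, with Hbb-bs at 623 ± 20.3 and Hba-a1 at 533 ± 2.21, whose near-identical copies Hbb-bt and Hba-a2 make the split between them uncertain. No T cell, neutrophil, thymus or proliferation marker reached a mean of 1 TPM. The highest were Cd3g at 0.230 ± 0.198, S100a8 at 0.320 ± 0.0141, Ptcra at 0.0150 ± 0.0212 and Top2a at 0.455 ± 0.276. In the B cell list only Ighm did, at 3.85 ± 1.69.

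**Figure D1:**
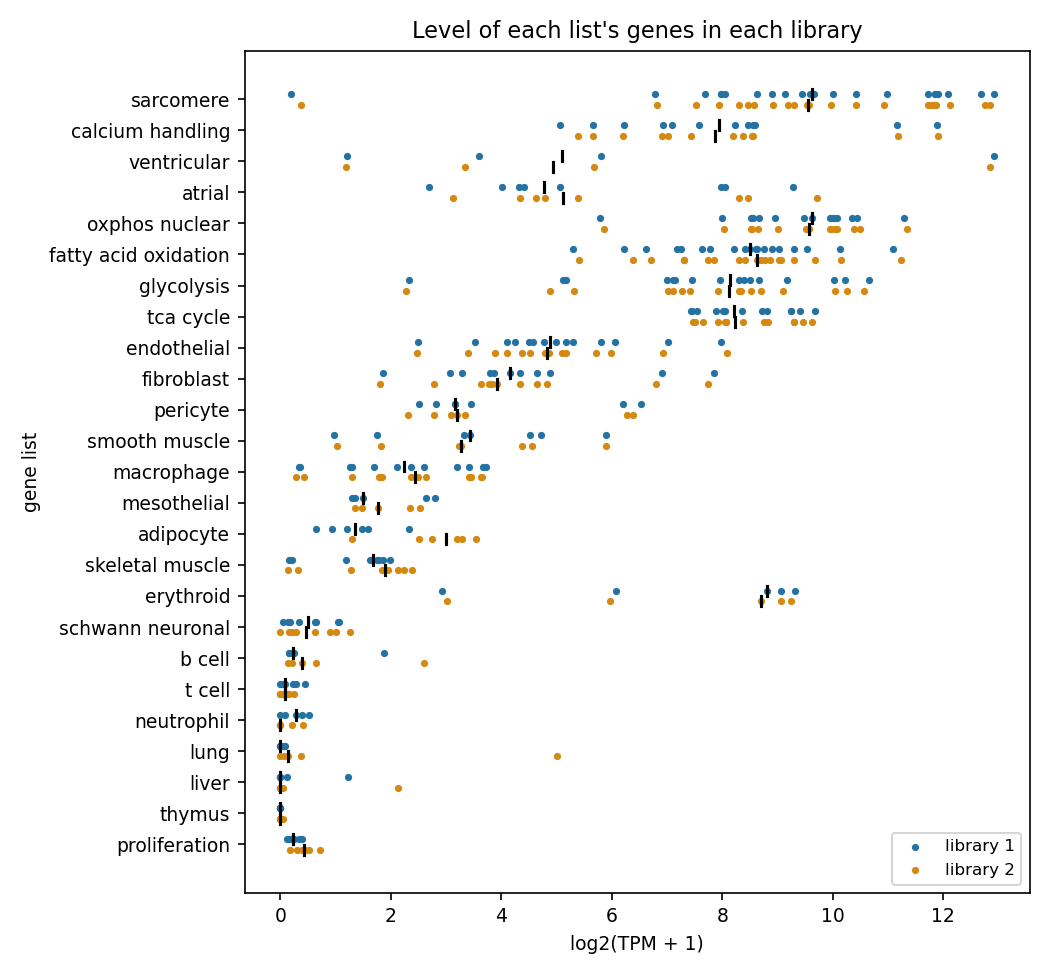
Level of each gene of 25 fixed lists in library 1 (blue) and library 2 (orange), as log2(TPM + 1) on the horizontal axis, with one point per gene and a black bar at the list median. Contractile and energy genes lie far to the right of the stromal and immune markers, and the adipocyte and atrial medians and Scgb1a1 in the lung list lie further right in library 2.

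Endogenous mouse genes related to the transgenes were expressed at moderate levels. App (chromosome 16, 84949685 to 85173766, minus strand), the amyloid precursor, stood at 41.5 ± 0.735 TPM and Thy1 (chromosome 9, 44043384 to 44048579, plus strand) at 3.31 ± 0.658 (4.76 in the second quantification). The App relative Aplp2 was higher, at 124 ± 0.849, and Apoe stood at 88.1 ± 4.24. The human transgene sequences were not analysed here. Of the sex-linked genes, the Y-linked Ddx3y stood at 22.1 ± 0.0919 TPM, Eif2s3y at 18.9 ± 1.39, Uty at 6.15 ± 1.40 and Kdm5d at 3.40 ± 0.714. Xist had 1 expected count in library 1 and 4 in library 2.

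For 13 of the 17 genes chosen for isoform use, both quantifications named the same leading transcript in both libraries. Tpm1-205 held 96.7% ± 0.596 of Tpm1, Slc25a3-206 held 93.0% ± 0.341 of the phosphate carrier Slc25a3 and Ryr2-201 held 85.8% ± 0.526 of the ryanodine receptor Ryr2. Atp2a2-202 held 78.8% ± 0.0958, Fhl1-201 72.8% ± 0.764, Ldb3-203 68.6% ± 0.705, App-203 57.4% ± 1.36, Mef2d-201 53.4% ± 2.47 and Pkm-202 51.8% ± 1.84 of their genes. No transcript passed 50% for Camk2d, led by Camk2d-202 at 44.8% ± 0.453, or Vegfa, led by Vegfa-202 at 37.7% ± 4.00. The same held for the giant sarcomere protein Ttn, led by Ttn-201 at 35.7% ± 0.655, and Nebl, led by Nebl-208 at 29.8% ± 0.845. Nebl-208 is a processed transcript of 436 bases, not annotated as protein coding, and TPM is divided by length. These shares are of the first quantification. In the second they moved both ways, with Tpm1-205 at 71.4% ± 0.339, Camk2d-202 at 31.8% ± 4.44 and Nebl-208 at 35.1% ± 0.559. The tables differed for Tnnt2, Cacna1c, Mbnl1 and Mef2c. Tnnt2-211 held 70.3% ± 2.30 of Tnnt2 in the first quantification and 18.7% ± 4.55 in the second, which placed Tnnt2-214 first with 30.5% ± 1.91. Cacna1c-218, a processed transcript of 954 bases not annotated as protein coding, led the first quantification with 33.9% ± 0.607. The protein-coding Cacna1c-212, of 7507 bases, led the second with 30.5% ± 0.245. Mbnl1-221 led with 20.2% ± 0.819 and Mef2c-212 with 22.2% ± 4.82 when averaged over the libraries, but not in every table.

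The replicates were close. In all, 11650 annotated genes had a TPM of at least 1 in both libraries, of which 10767 were protein coding. A further 387 genes passed in library 1 alone and 340 in library 2 alone. Across 12377 genes with TPM of at least 1 in either library, Pearson's r of log2(TPM + 1) was 0.985 and Spearman's rho 0.981. Genes are not independent replicates, so no p-value was attached. Of 11940 genes tested for a 2-fold ratio, 72 passed it, 45 higher in library 2 and 27 higher in library 1, and Poisson sampling alone gave 3.11 on average over 100 draws. The second quantification gave 48 and 50, a pseudocount of 0.1 gave 78 and 74, and scaled expected counts gave 67 and 52 (TMM). Only 25 of the 72 also passed 2-fold the same way in the second quantification. That subset held 19 of the 26 protein-coding genes, 5 of the 24 pseudogenes and 0 of the 19 small RNAs. The second quantification listed all 19 small RNAs, and many of the pseudogenes, below 1 TPM in both libraries. With 1 added to each TPM, such entries could not reach a 2-fold ratio there. Their absence from the subset thus says nothing about the first quantification. The common biological coefficient of variation was 0.0624 (edgeR). The counts differed by more than counting noise, with a chi-square of 5.35 per degree of freedom over 17147 genes, so they are not one library deposited again. This does not show that they came from separate animals. Spike-in RNAs held 0.370% ± 0.0146 of the expected counts. Over 24 spike-ins with at least 100 counts in both libraries, the log2 ratio of their share had an SD of 0.102, against 0.160 for 10177 protein-coding genes.

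**Figure D2:**
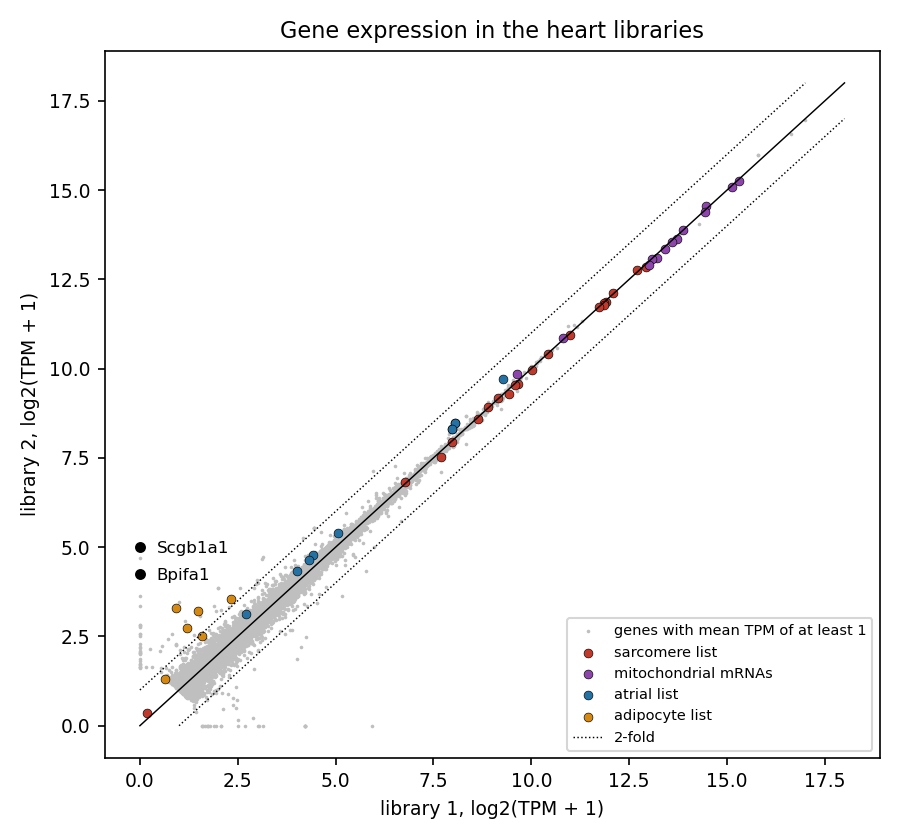
Expression of each gene with mean TPM of at least 1 in library 1 (horizontal axis) and library 2 (vertical axis), both as log2(TPM + 1). The solid line marks equal values and the dotted lines a 2-fold ratio, and the adipocyte genes, Scgb1a1 and Bpifa1 lie above the solid line while sarcomere genes and mitochondrial mRNAs lie along it.

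Fat, atrial and lipid genes were higher in library 2. All 6 adipocyte markers were higher there, with a median log2 ratio of 1.37, including Cfd at 4.04 and 10.6 TPM in library 1 and library 2, the lipid droplet coat protein Plin1 at 1.79 and 8.21, the thermogenic uncoupling protein Ucp1 at 0.900 and 8.74 and Cidec at 1.3 and 5.69. All 8 atrial markers were higher in TPM, with a median of 0.35, among them Nppa at 617 and 842 TPM. The light chains Myl4 and Myl7 stood at 263 and 355 and at 251 and 313, and the calcium pump regulator Sln at 32.5 and 40.8. For Gja5 the count ratio was 1.11, with a 95% exact interval of 0.972 to 1.27 that includes 1. The 4 ventricular markers had log2 ratios below 0, among them Irx4 at 11.1 and 9.11. The exact intervals included 1 for Hey2, with a count ratio of 0.992 (0.745 to 1.32), and Kcnip2, with 0.969 (0.924 to 1.02). Myl2 and Hey2 were not lower in the second quantification. Of the targets of the lipid-sensing PPAR receptors, 8 of 9 members above 1 TPM were higher, with a median of 0.36, such as the pyruvate dehydrogenase kinase Pdk4 at 90.8 and 153 TPM and the uncoupling protein Ucp3 at 17.7 and 25.7. In the fatty acid oxidation list 17 of 19 members were higher, by a median of 0.10. Each of these 4 lists lay at percentile 100 of 10000 random lists matched on expression.

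Clock, heat shock, skeletal muscle and non-coding RNA lists also lay above the range that holds 95% of random lists, and endothelial, immediate early and hypertrophy lists below it. In the circadian list, 10 of 13 members were higher in library 2 (median 0.16), with Dbp at 57.7 and 64.6 TPM and Per2 at 4.36 and 5.92, while the clock repressor Nr1d1 went the other way, at 31.0 and 21.4. Heat shock genes had a median of 0.13, with Hspd1 at 118 and 129, and skeletal muscle genes, led by Tnnt3 at 2.98 and 3.73 TPM, a median of 0.23. Of the 6 skeletal muscle members, only Myh4 had an exact interval of its count ratio that excluded 1 (1.08 to 1.41). Non-coding RNAs had a median of 0.17 but only 5 of 9 members higher, among them the equal copies Rn7s1 and Rn7s2 at 56400 and 64395, while Rn7sk went the other way, at 15808 and 14849. Immediate early genes had a median of -0.21, with Dusp1 at 16.3 and 13.8 TPM and Egr1 at 2.86 and 1.93, but 3 of 9 members were higher in library 2, among them Jun at 12.2 and 17.7. Endothelial genes had a median of -0.09 with 2 of 14 members higher, and hypertrophy genes -0.08 with 3 of 10 higher. In all, 11 of 29 lists lay outside the range of random lists, against 1.45 by chance. Genes of a list vary together, so these percentiles describe the 2 libraries and are no test. The circadian, endothelial and hypertrophy lists were inside the range in the second quantification, and the hypertrophy list also with a pseudocount of 0.1. With scaled expected counts in place of TPM, an alternative chosen after seeing the data, the non-coding RNA list was inside the range and the erythroid list below it.

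**Figure D3:**
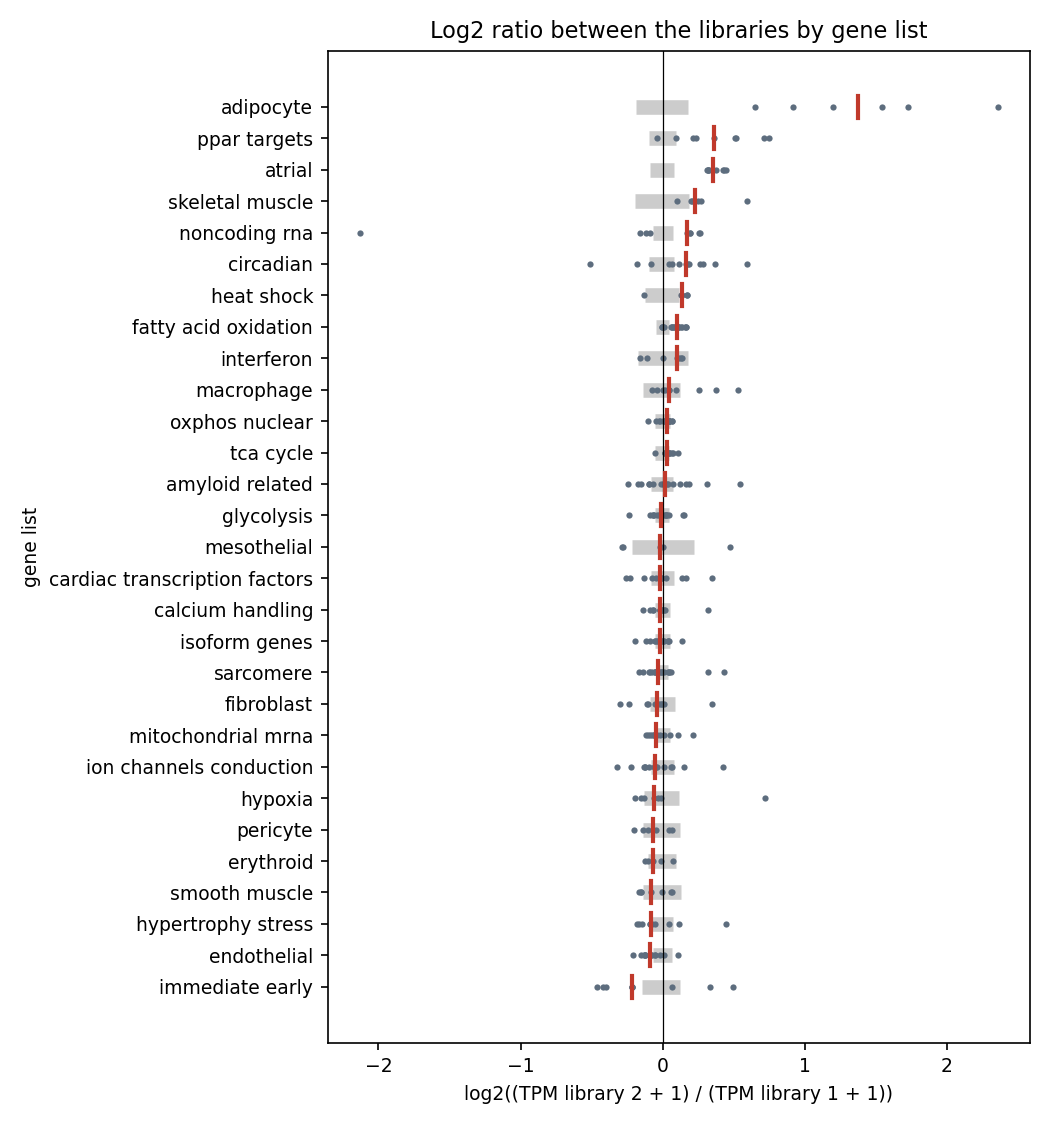
Log2 ratio of library 2 to library 1, as log2((TPM + 1)/(TPM + 1)), for the 29 lists with at least 5 genes above a mean of 1 TPM. Grey points are genes, red bars list medians and grey bands the range that holds 95% of the medians of random lists, and the adipocyte list stands furthest out with a median of 1.37.

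Among 7201 genes with a mean TPM of at least 5 and at least 100 counts in the higher library, 2 airway genes differed most. Scgb1a1 (chromosome 19, 9083636 to 9087958, minus strand), the main secretory protein of airway club cells, had 0 expected counts in library 1 and 366 in library 2, at least 131-fold higher per count total. Bpifa1 (chromosome 2, 154142880 to 154149219, plus strand), a secreted airway protein, had 0 and 564, at least 202-fold higher. These bounds set library 1 at the 3 counts that a count of 0 allows and leave out counting error in library 2. The exact 95% intervals of the count ratio began lower, at 106 for Scgb1a1 and 164 for Bpifa1. Ratios of expected counts followed for Plin1, at 4.96 (95% exact interval 3.90 to 6.36), the desaturase Scd1, at 4.11 (3.80 to 4.45), the carbonic anhydrase Car3, at 3.33 (2.98 to 3.73), Cfd, at 2.69 (2.14 to 3.39), and Cbr2, at 2.21 (1.81 to 2.70). The intervals cover counting error only. The mitochondrial copy Gm10222 and the U3 small nucleolar RNA genes Rnu3b1 to Rnu3b4 completed this side. The U3 genes are annotated as 8 entries at 4 loci, and their summed expected counts were 584 and 659, at 152 and 182 summed TPM. The difference of single entries was thus largely one of assignment, with a smaller difference left in the sum.

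On the library 1 side, Rrad, a GTPase that restrains calcium channels, stood at 101 and 52.5 TPM in library 1 and library 2, with a count ratio of 0.532 (0.506 to 0.560). Tcf15, an endothelial transcription factor of heart capillaries, stood at 15.1 and 9.14, with a count ratio of 0.611 (0.522 to 0.716), and Fyb, an adaptor protein of blood cells, at 16.4 and 3.62, with 0.285 (0.219 to 0.366) and 5.57 and 2.18 TPM in the second quantification. Hmga1b and Ston1 had count ratios of 1.06 and 0.977, so that their TPM difference came from the lengths of the transcripts assigned. The second quantification repeated it for Ston1, at 6.48 and 3.45 TPM, but not for Hmga1b, at 7.93 and 7.71. Gm5537, Gm12070, Gm10241 and Gm8325 are pseudogenes that were listed below 1 TPM on average in the second quantification. Pagr1a had 159 and 34 counts at 7.07 and 3.25 TPM, and 10.4 and 4.24 TPM in the second quantification.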

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

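The tests of alveolar tissue and of depth or scaling were chosen only after the result was seen. That of depth or scaling replaced earlier forms whose outcome TPM scaling or the choice of the list had fixed. Its last form still drew on the counts of the flagged list itself. The phiX entry, a sequencing control genome that the comparisons did not use, had 187 expected counts in library 1 and 216 in library 2, above the 3 that a count of 0 allows.

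Scgb1a1 and Bpifa1 were counted in library 2 and not in library 1. A candidate explanation is that airway lining cells were carried over with the tissue of library 2. In a second list of 12 airway genes, written before their values were seen, 10 had more expected counts in library 2, with 442 counts over the list against 69, and only 1 of the 12 was above 1 TPM in library 1. Among these, the club cell enzyme Cyp2f2 had 11 and 188 counts, the secretoglobin Scgb3a2 had 0 and 37 and the mucin Muc5b had 0 and 40. Alveolar lung tissue in the same sample stays open: Sftpc, an abundant transcript of alveolar type II cells, had 0 counts in library 2, Sftpb had 2 and 2 in library 1 and library 2, and Ager had 3 and 4, which go against it, but the surfactant gene Sftpa1 had 0 and 10. Whether the reads came with the tissue or arose during library handling was not tested, and no biological explanation was tested, since the design holds a single group.

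The adipocyte list was higher in library 2. The log2 ratio of the count totals was -0.103, so the difference in total depth went the other way and was far smaller than the list median of 1.37. The expected counts of its members, without any scaling, had a median log2 ratio of 1.94. These counts underlie the TPM values for which the list was flagged, so they are no separate evidence on scaling. Fat tissue carried over with the tissue of library 2 may account for the higher list and stays open. A second list of fat genes had a median of 0.26, between the bounds set beforehand, with 12 of 14 members higher. All 14 were above 1 TPM in library 1, so the level already there could hide an added share. Single members do not stand for the list. Pck1 had 105 and 526 counts, a log2 ratio of 1.76 that lay far above the list median. Adrb3, outside the members above 1 TPM, had 1 and 14 counts. A difference between the samples in the lipid genes of heart cells was not tested.

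The atrial list was also higher in library 2. A bias by GC content or length is argued against, since the median log2 ratio was 0.35 before and 0.36 after the trend on both was removed over all genes, with values for 8 of 8 members. More atrium in the tissue of library 2 may be the source. A second atrial list had a median of 0.012, below the bound of 0.05 set beforehand, so by that rule it came out against more atrium. The margin was smaller than the standard error of 0.109 from the spread of its members. That error was not part of the rule and takes genes of a list as independent. With 3 of 6 members higher, the members went both ways, and this small list does not decide the question.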

How the results depend on the processing

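Of 36 alternatives other than single libraries, 14 left their result within its spread, or a count within 1.5 times its main value. Alternatives with airway and fat genes left out, chromosome 1 copies added, full-length myosin transcripts, rescaling to nuclear protein-coding genes and scaled counts for lists were chosen after seeing the data. In the second quantification the genes over 2-fold split 48 to 50 in place of 45 to 27, and the medians of 5 of 29 lists changed sign, none of them larger than 0.0663 in the first. By scaled counts 5 changed sign, among them the non-coding RNA list. Genes detected were 7079 at a minimum of 5 TPM. The correlation was 0.963 with a pseudocount of 0.1, 0.993 with 5, 0.995 without a filter and 0.984 in the second quantification. Genes over 2-fold were 152 with a pseudocount of 0.1, 24 with 5, 159 without a filter, 119 by TMM and 126 by DESeq2 size factors. The coefficient of variation was 0.0695 without the filter and 0.0564 for counts of at least 100. The mitochondrial mRNA share was 14.8% by expected counts and 27.1% with the copies added. The sarcomere share was 12.8% by expected counts, 12.9% of nuclear protein-coding TPM and 8.43% in the second quantification. The Myh6 share was 94.8% by expected counts, 95.8% over full-length transcripts and 83.3% in the second quantification. The light chain ratio was 0.0208 in the second quantification. That quantification listed Myl2 at 13390 TPM, of which the short entry Myl2-210 held 7594. The spike-in share was 0.572% of TPM. Counts are not divided by length, by construction, and the cause of the other differences was not tested. Each library alone lies within 1 SD of a mean of 2 by construction, so leaving one out says nothing about stability. Correlation, 2-fold counts, variation and lists need both libraries and have no such value. No paired analysis was possible because there is a single group. Depth limits genes near 1 TPM, where a few counts decide detection.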

Other observations

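Genes linked to the amyloid pathway went both ways between the libraries, with 9 of 17 members higher in library 2, a list median log2 ratio of 0.01 and members from -0.245 (Tyrobp) to 0.546 (Mme). Among secretase genes, Aph1a stood at 36.5 ± 0 TPM, Psenen at 29.2 ± 1.80, Ncstn at 14.9 ± 0.523 and Bace1 at 10.6 ± 0.877, and the tau gene Mapt stood at 29.2 ± 2.72. Interferon genes were low, led by Ifi27l2a at 9.99 ± 0.615. Hypoxia genes stood at a median of 12.4 ± 0.887, led by Bnip3 at 72.4 ± 0.460 and Vegfa at 58.2 ± 5.59.

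The genes over 2-fold in both quantifications, named after their values were seen, included 2 higher in library 1, Fyb and the retinoic acid hydroxylase Cyp26b1, at 6.49 and 2.00 TPM. Among the 23 higher in library 2 were the secretory protein Ltf, with 0 and 237 counts, the cytochrome Cyp2a5, with 0 and 139, the immunoglobulin light chain Igkc, with 20 and 75, and haptoglobin, Hp, with 63 and 187. In the liver list only Cyp2e1 was above 1 TPM, at 2.37 ± 1.45. The core clock gene Arntl had 73 counts in library 1 and 29 in library 2, the opposite direction to Per2, with 804 and 1058.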
